A study of Mus musculus with 6 samples.

How the data were processed

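The series holds 6 bulk RNA-seq libraries of mouse cells labelled as temporomandibular joint condylar chondrocytes, the cartilage cells of the jaw joint's condyle. Per the labels, 3 libraries came from cells transfected with a small interfering RNA against RalA (siRalA) and 3 from cells transfected with a negative control (siNC), whose library names and genotype field call them wild type. The labels describe total RNA sequenced as paired-end reads on an Illumina NovaSeq instrument. They name no stimulation, batch, day, litter or siRNA sequence. Nothing in them says that replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

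The deposited table gives whole-number counts per Ensembl gene ID, one column per library, with no normalization. The submitters' processing notes name the genome build GRCm39. The aligner, the counting tool, the annotation release, the strand setting and any filter are not given in the sources used here. Low counts in the deposited table were unevenly distributed. In the library siNC 1, 532 genes had 3 counts, 1157 had 4 and 361 had 5, and like excesses stood at 8 and 12 in every library. A count is therefore not taken to equal 1 sequenced fragment, whether the counts were tallied directly or estimated is not shown, and no interval based on counting is given. Column totals ranged from 63555407 to 66965318 counts. All 6 columns matched a library name in the labels, and no column was left over.

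Gene symbols came from a GENCODE annotation of an earlier mouse build than the one the submitters name. It was used for symbols and for transcript sequences only, and no coordinates are printed for that reason. Of 57132 gene IDs, 51880 had a symbol, as did 18533 of the 19073 genes tested. IDs without a symbol held 0.27 to 0.32% of the counts. Because the strand setting is unknown, reads from a gene and an overlapping antisense gene cannot be told apart.

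Counts were tested with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood F test (glmQLFit and glmQLFTest), TMM scaling, filterByExpr with its minimum count of 10, and a model with an intercept and the group. Adjusted p-values are Benjamini-Hochberg values over all 19073 genes tested, and a gene was called at an adjusted p under 0.05. Levels are CPM, counts scaled to a common total with the TMM-scaled library sizes, given as mean ± SD of 3 libraries per group. Log2 fold changes are siRalA minus siNC, with the standard error (SE) of the fit. Principal components used log2 CPM with a prior count of 2. A gene at 0 in every library of a group was set against a floor of 3 counts per library.

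A total of 40 gene lists, covering pathways, RNA quality and markers of other cell types, were fixed before the data were examined. The members at an adjusted p under 0.05 were counted over all genes tested and adjusted over the list alone. Each list with at least 3 tested members was tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes, which asks whether members move against other genes. The same test with an estimated correlation and the fry test, which asks whether members move on balance one way, were run beside it. List p-values are adjusted over the 39 lists tested. The erythroid list had no tested member.

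The genes named were chosen by a rule fixed before the data were examined. It takes Rala, Ralb and Ccn3, and then the 10 largest rises and 10 largest falls among called genes with a mean above 5 CPM and no overlap between groups, leaving out predicted or unnamed genes. From each list it takes up to 4 called members with the smallest p, or up to 2 abundant members where none passed. Clone-style symbols were left out as well, which changed neither set of 10. One gene that the rule takes is not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

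Alternatives planned before the data were examined were the DESeq2 1.42.0 Wald test, limma-voom, size factors of the DESeq2 type (RLE), upper quartile scaling, library size only, no filter on low counts, a filter of 1 CPM in 3 libraries, a test against a 1.5-fold change (glmTreat), the replicate number as a block, and leaving out each library in turn. Counts divided by 4 were added after the data were seen. The edgeR step was tested on simulated counts for the siRalA and siNC comparison over 19073 genes, with 50 genes changed at each fold. It recovered 16% of genes changed 1.25-fold, 30% at 1.5-fold, 58% at 2-fold and 72% at 4-fold, with 5 false calls. DESeq2 recovered 28, 44, 72 and 80% with 30 false calls, and voom 12, 30, 56 and 70% with 5. The changed genes were a small part of those simulated, whereas 51.1% of tested genes were called in the real comparison. The adjusted p is therefore stricter in the simulation, and these rates do not carry over to the data. In simulated data with one raised list, camera called 0 of 39 unchanged lists. Genes were simulated independently, so this does not show how camera behaves on lists of correlated genes. Estimated correlations in the real lists reached 0.81, in the interferon list.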

Results

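Expression was profiled by bulk RNA-seq in 6 libraries of cells labelled as mouse condylar chondrocytes, 3 transfected with siRalA and 3 with siNC. The series title links the small GTPase RalA to secretion of the matricellular protein CCN3 and to inflammatory matrix breakdown in osteoarthritis of the jaw joint, and the comparison asks which transcripts differ when RalA is targeted. Totals ranged from 63555407 to 66965318 counts, and the mean total in siRalA libraries was 1.01 times that in siNC libraries. Between 24098 and 24326 genes were detected per library. Mitochondrial transcripts held 2.7 to 2.9% of counts, and the 10 most abundant genes held 9.3 to 9.6% in siNC and 7.4 to 8.0% in siRalA libraries. Correlations of log2 CPM across genes were 0.982 to 0.986 within groups and 0.946 to 0.954 between groups, and the first principal component, with 64.8% of the variance, separated the groups. Between libraries of a group, chi-square values were 10.2 to 21.0 per degree of freedom, where independent counts would give about 1. A count is not taken to equal 1 fragment, however, so the sampling noise itself is unknown.

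The targeted gene was modestly lower in every siRalA library. Rala (ENSMUSG00000008859) stood at 42.0, 42.1 and 46.3 CPM in the siNC libraries and at 33.6, 35.7 and 31.9 CPM in the siRalA libraries. The means were 43.5 ± 2.47 and 33.7 ± 1.88 CPM (SD, n = 3 each), so that siRalA libraries held 77.6% of the siNC level, with a log2 fold change of -0.37 (SE 0.064, edgeR adjusted p = 8.8e-04). With library size only the log2 fold change of Rala was -0.17 and its edgeR adjusted p 0.051, while over the other settings the adjusted p ranged from 1.3e-06 to 0.0055. Among 19073 tested genes, 4831 were called lower, 1613 of them by at least 2-fold, and 60.3% did not overlap between the groups. The fall of Rala therefore does not by itself show a knockdown. The close paralog Ralb (ENSMUSG00000004451) was at 36.5 ± 0.952 CPM in siNC and 38.4 ± 0.141 CPM in siRalA libraries and did not pass (edgeR adjusted p = 0.25), although with library size only it rose by 0.27 on the log2 scale (edgeR adjusted p = 0.0010).

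Among 16 tested Ral GTPases, regulators and effectors, 4 were higher and 7 lower, and 11 passed when adjusted over the list alone. Of all tested genes 51.1% were called, so a list count near that share is not particular to the list. Reps2 rose from 2.97 ± 0.456 to 10.2 ± 1.36 CPM. Ralgapa2, a subunit of a GTPase-activating complex for Ral, fell from 22.9 ± 1.78 to 12.1 ± 1.21 CPM. In the exocyst, the vesicle-tethering complex that Ral proteins bind, 4 of 9 members were higher and 2 lower, or 4 and 1 with library size only, with 6 passing adjusted over the list alone. Exoc3 rose from 47.2 ± 1.95 to 99.4 ± 5.58 CPM and Exoc4 fell from 174 ± 9.58 to 132 ± 1.34 CPM. Neither list was called as a set (camera adjusted p = 0.99 and 0.43), and with library size only the Ral list turned to 7 higher and 1 lower.

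Ccn3 (ENSMUSG00000037362), the gene of the secreted protein in the title, was higher in siRalA libraries. It stood at 41.2, 41.7 and 37.2 CPM in siNC and at 97.1, 113 and 123 CPM in siRalA libraries. The means of 40.0 ± 2.47 and 111 ± 13.2 CPM (SD, n = 3 each) gave a 2.77-fold rise in Ccn3 with a 95% interval of 2.43 to 3.16 (log2 fold change 1.47, SE 0.085, edgeR adjusted p = 4.4e-07). Transcript was measured here, and secreted protein was not analysed here. Of the 6 members of the CCN family, 4 rose and 0 fell, and 5 passed adjusted over the list alone. Ccn5 rose from 513 ± 37.5 to 999 ± 12.8 CPM, Ccn4 from 56.3 ± 1.63 to 70.5 ± 5.61 CPM and Ccn1 from 438 ± 5.37 to 496 ± 15.0 CPM. The CCN list was called higher (camera adjusted p = 0.0045), and its adjusted p was 0.14 with an estimated correlation.

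Among called genes above 5 CPM with no overlap between the groups, predicted and unnamed genes left out, Nos2 fell the most and Ibsp rose the most. Nos2 (ENSMUSG00000020826), the inducible nitric oxide synthase, fell from 2103 ± 229 to 1.11 ± 0.387 CPM (log2 fold change -10.89, SE 0.18, edgeR adjusted p = 4.2e-10). Mmp3, the protease stromelysin-1, fell from 14814 ± 832 to 390 ± 113 CPM, and the cytokine gene Il6 from 236 ± 12.1 to 2.56 ± 0.843 CPM. Ibsp, a bone matrix sialoprotein gene, rose from 3.28 ± 0.765 to 77.7 ± 13.8 CPM, and Fzd9, a Wnt receptor gene, from 2.29 ± 0.229 to 49.4 ± 7.15 CPM. The imprinted gene Mest rose from 192 ± 34.5 to 3339 ± 107 CPM.

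The other genes among the 10 largest falls, with their log2 fold changes, were Csf3 (-6.75), Mmp10 (-6.59), Cxcl2 (-6.47), Tnfrsf9 (-6.05), Il13ra2 (-5.92), Glt1d1 (-5.32) and H2-Q2 (-7.99). H2-Q2 is a class I histocompatibility gene, 32.8% of whose 31-base words also occur in transcripts of other genes, so its value is uncertain. Also among the 10 largest rises were Galnt9 (4.29), Matn3 (4.08), Gdf10 (3.31), Atp6v0a4 (3.26), Omd (3.11) and Msmp (3.11). Across 19073 tested genes, 4914 were higher and 4831 lower, a split of 50.4% higher among 9745 calls. With library size only, which shifted the median log2 fold change by 0.20, the split was 69.9% higher, with 7648 genes higher and 3288 lower. By at least 2-fold, 964 genes were higher and 1613 lower, and by at least 4-fold 224 were higher and 544 lower. The libraries of the groups did not overlap for 60.3% of tested genes, where chance gives 10%.

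**Figure D1:**
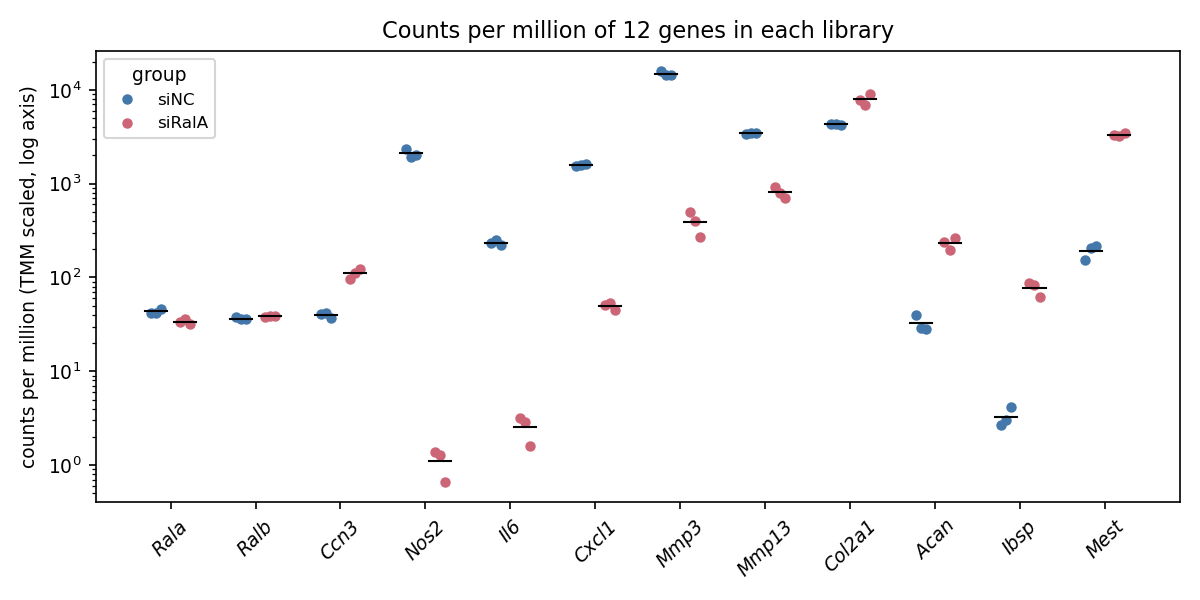
CPM on a log axis for 12 genes in each siNC (blue) and siRalA (red) library, with points for single libraries, lines for the group means of 3 libraries, and Mmp13, Col2a1 and Acan added to the genes of the naming rule after their values were seen. Rala moved from a mean of 43.5 to 33.7 CPM while Nos2 moved from 2103 to 1.11 CPM and Ccn3 from 40.0 to 111 CPM.

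Inflammatory cytokine and chemokine genes fell together in siRalA libraries. Of 26 tested members, 0 rose and 23 fell, and 1 rose and 23 fell with upper quartile scaling and with library size only. Adjusted over the list alone 25 passed, 24 lower and 1 higher. The higher one, Cxcl12, chosen after its values were seen, was at 1307 ± 262 CPM in siNC and 1636 ± 125 CPM in siRalA libraries (edgeR adjusted p = 0.052 over all genes). The neutrophil chemokine gene Cxcl1 fell from 1582 ± 41.3 to 49.7 ± 4.70 CPM, Lif, an interleukin-6 family cytokine, from 119 ± 11.4 to 3.79 ± 0.455 CPM, and the monocyte chemokine gene Ccl7 from 465 ± 18.9 to 61.6 ± 4.75 CPM. The list median was -3.18 on the log2 scale, also with Csf2, singled out because it was at 0 in every siRalA library and at least 17.7-fold lower, set to its bound (camera adjusted p = 1.6e-52, and adjusted p = 0.0056 with an estimated correlation). Chosen after their values were seen, the acute phase gene Saa3 fell from 7718 ± 481 to 648 ± 93.4 CPM and Lcn2 from 5481 ± 410 to 779 ± 91.5 CPM. Il1b and Tnf, chosen likewise, were at 0.379 ± 0.262 and 1.18 ± 0.336 CPM in siNC libraries. In the same libraries, the 17 tested macrophage and osteoclast markers, most of whose counts came from Lyz2, summed to 1506 ± 51.9 CPM in siNC and 1180 ± 125 CPM in siRalA, while 8 lineage genes among them, chosen after the data were seen, summed to 146 ± 7.12 and 187 ± 18.4 CPM.

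Genes of the NF-kB pathway and its feedback were lower as well. Of 27 tested, 1 rose and 25 fell, with 26 passing adjusted over the list alone. Nfkbia, the inhibitor that NF-kB induces, fell from 220 ± 7.73 to 23.7 ± 2.43 CPM, Sod2, a mitochondrial superoxide dismutase, from 478 ± 18.0 to 78.8 ± 6.43 CPM, and Tlr2, a receptor for bacterial lipoproteins, from 137 ± 3.42 to 30.3 ± 2.24 CPM (camera adjusted p = 1.7e-32, and adjusted p = 0.0056 with an estimated correlation). In prostaglandin and nitric oxide synthesis, 5 of 14 genes rose and 8 fell, or 5 and 7 with library size only, where the median moved from -0.47 to -0.28, with 13 passing adjusted over the list alone. Ptgs2, the inducible cyclooxygenase, fell from 659 ± 116 to 18.5 ± 4.04 CPM, Ptges, a prostaglandin E synthase, from 335 ± 4.79 to 41.6 ± 1.03 CPM, and Pla2g4a, a phospholipase that releases arachidonic acid, from 171 ± 1.56 to 45.02 ± 3.65 CPM (camera adjusted p = 8.0e-10, and adjusted p = 0.025 with an estimated correlation). Among 27 MAPK feedback and immediate early genes, 2 rose and 17 fell, with 19 passing adjusted over the list alone. Fosl1, an AP-1 subunit, fell from 57.2 ± 5.75 to 7.998 ± 0.899 CPM and Ier3 from 473 ± 113 to 53.2 ± 1.51 CPM (camera adjusted p = 5.8e-07, and adjusted p = 0.13 with an estimated correlation).

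Matrix-degrading proteases were mostly lower and cartilage matrix genes mostly higher in siRalA libraries. Of 29 proteases, 6 rose and 18 fell, or 8 and 15 with library size only, where the median moved from -0.38 to -0.18, with 24 passing adjusted over the list alone. Besides Mmp3, the macrophage elastase gene Mmp12 fell from 548 ± 68.1 to 60.6 ± 7.38 CPM, Adamts1 from 289 ± 10.9 to 108 ± 5.89 CPM and Adamts7 from 71.9 ± 8.91 to 12.4 ± 1.18 CPM (camera adjusted p = 5.6e-08, and adjusted p = 0.081 with an estimated correlation). Chosen after their values were seen, the collagenase gene Mmp13 fell from 3442 ± 70.6 to 806 ± 111 CPM and the aggrecanase gene Adamts5 from 594 ± 45.6 to 235 ± 10.8 CPM. Of 10 protease inhibitors, 4 rose and 4 fell, or 5 and 4 with library size only, with 8 passing adjusted over the list alone (camera adjusted p = 0.22). Timp1 fell from 1303 ± 56.6 to 542 ± 34.1 CPM, while Timp3 rose from 636 ± 67.2 to 1704 ± 97.6 CPM.

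Of 30 cartilage matrix genes and chondrogenic regulators, 20 rose and 7 fell, with 27 passing adjusted over the list alone. Matn4, a matrilin, rose from 16.3 ± 1.90 to 82.6 ± 6.91 CPM, Col9a1 from 118 ± 5.87 to 264 ± 11.9 CPM and Col11a1 from 643 ± 19.1 to 1332 ± 77.3 CPM, and Prg4, the joint lubricant lubricin, fell from 372 ± 12.1 to 123 ± 3.27 CPM (camera adjusted p = 4.6e-07, and adjusted p = 0.27 with an estimated correlation). Chosen after their values were seen, Col2a1, the main cartilage collagen, rose from 4279 ± 49.0 to 7945 ± 1046 CPM, Acan, the aggrecan core protein, from 32.5 ± 6.57 to 232 ± 31.9 CPM, and the transcription factor Sox9 from 40.1 ± 5.49 to 128 ± 4.27 CPM. The 7 that fell included, chosen likewise, Col9a2 (47.8 ± 1.33 to 36.3 ± 3.71 CPM), Col9a3 (82.2 ± 4.70 to 68.6 ± 7.35 CPM) and Matn1 (40.2 ± 6.05 to 19.8 ± 1.85 CPM). The hypertrophy and mineralization list went both ways, with 11 of 18 higher and 5 lower and 16 passing adjusted over the list alone (camera adjusted p = 0.22). In it the angiogenic factor Vegfa fell from 746 ± 46.4 to 144 ± 5.88 CPM and the phosphatase Phospho1 from 28.6 ± 6.17 to 4.14 ± 0.591 CPM, while Smpd3 rose from 3.38 ± 0.533 to 13.6 ± 1.17 CPM. Of 32 fibrous collagens and modifying enzymes, 6 rose and 20 fell, or 10 and 18 with library size only, where the median moved from -0.39 to -0.19, with 26 passing adjusted over the list alone. Loxl2, a collagen cross-linking enzyme, fell from 1137 ± 41.7 to 253 ± 14.3 CPM, Col5a3 from 475 ± 5.45 to 83.9 ± 6.80 CPM and Tnc from 892 ± 22.7 to 320 ± 14.4 CPM (camera adjusted p = 7.7e-10, and adjusted p = 0.19 with an estimated correlation). In the same libraries, skeletal muscle and adipocyte markers were higher in siRalA, as given with the cell type markers.

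Genes of the p53, oxidative stress and glycolysis lists were mostly lower, and cell cycle and cholesterol synthesis genes mostly higher, in siRalA libraries. Of 23 p53 targets and senescence genes, 2 rose and 19 fell, with 22 passing adjusted over the list alone. Cdkn1a, the cell cycle inhibitor p21, fell from 1155 ± 40.3 to 319 ± 12.8 CPM, Mdm2 from 488 ± 23.2 to 113 ± 5.42 CPM and the stress cytokine gene Gdf15 from 67.0 ± 4.05 to 7.22 ± 0.657 CPM (camera adjusted p = 8.3e-31, and adjusted p = 0.014 with an estimated correlation). Of 22 NRF2 and oxidative stress genes, 1 rose and 16 fell, with 18 passing adjusted over the list alone. Slc7a11, a cystine transporter, fell from 54.5 ± 0.582 to 4.26 ± 0.295 CPM, Hmox1, a haem oxygenase, from 1152 ± 86.3 to 324 ± 4.46 CPM and the metallothionein gene Mt1 from 1093 ± 77.8 to 145 ± 13.3 CPM (camera adjusted p = 1.1e-26, and adjusted p = 0.0056 with an estimated correlation). All 25 tested glycolysis and hypoxia genes fell and 25 passed adjusted over the list alone. Egln3, an oxygen sensor, fell from 121 ± 13.8 to 13.04 ± 1.66 CPM, Adm from 491 ± 19.2 to 114 ± 8.45 CPM and Pfkfb3 from 341 ± 14.1 to 122 ± 6.07 CPM (camera adjusted p = 1.2e-34, and adjusted p = 0.081 with an estimated correlation).

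Of 34 cell cycle genes, 31 rose and 1 fell, with 32 passing adjusted over the list alone. The replication helicase genes Mcm6 and Mcm2 rose from 30.7 ± 1.31 to 93.6 ± 4.21 CPM and from 18.9 ± 0.823 to 56.6 ± 1.39 CPM, and the mitotic kinase gene Plk1 from 16.9 ± 0.647 to 46.5 ± 1.74 CPM (camera adjusted p = 1.0e-27, and adjusted p = 0.081 with an estimated correlation). Of 24 cholesterol genes, 21 rose and 0 fell, with 21 passing adjusted over the list alone. Idi1 rose from 13.8 ± 1.51 to 40.3 ± 1.31 CPM and Cyp51 from 33.1 ± 3.14 to 87.1 ± 3.66 CPM (camera adjusted p = 7.4e-08, and adjusted p = 0.10 with an estimated correlation).

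Several signalling and adhesion lists moved by smaller amounts. Of 29 TGF-beta and BMP response genes, 9 rose and 15 fell, or 11 and 13 with library size only, where the median moved from -0.26 to -0.06, with 25 passing adjusted over the list alone, and Inhba, an activin subunit, fell from 208 ± 11.3 to 31.8 ± 2.97 CPM (camera adjusted p = 0.0060, and adjusted p = 0.10 with an estimated correlation). Of 23 Wnt genes, 10 rose and 6 fell, or 12 and 5 with library size only, where the median moved from 0.15 to 0.35, with 16 passing adjusted over the list alone (camera adjusted p = 0.0025, and adjusted p = 0.19 with an estimated correlation). Dkk3 rose from 242 ± 5.40 to 626 ± 25.7 CPM and Frzb, a secreted Wnt antagonist, from 12.1 ± 0.723 to 47.5 ± 1.14 CPM. Of 19 YAP/TAZ-TEAD targets, 2 rose and 11 fell, or 6 and 9 with library size only, where the median moved from -0.29 to -0.10, with 13 passing adjusted over the list alone, and Gadd45b fell from 88.6 ± 3.38 to 34.96 ± 1.19 CPM (camera adjusted p = 9.8e-04, and adjusted p = 0.081 with an estimated correlation). Of 25 integrin and focal adhesion genes, 6 rose and 14 fell, with 20 passing adjusted over the list alone, and Itgav fell from 289 ± 13.5 to 147 ± 6.32 CPM (camera adjusted p = 0.045, and adjusted p = 0.18 with an estimated correlation). That call was lost with library size only (adjusted p = 0.20), where the median turned to 0.01, and without siNC replicate 1, siRalA replicate 1 or siRalA replicate 2 (adjusted p = 0.066, 0.065 and 0.073). Of 16 Notch genes, 3 rose and 5 fell, or 4 and 4 with library size only, with 8 passing adjusted over the list alone, and Notch3 fell from 124 ± 6.13 to 28.0 ± 2.82 CPM (camera adjusted p = 0.22).

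Lists of organelle and cell death genes gave mixed directions. Of 27 autophagy and lysosome genes, 5 rose and 15 fell, with 22 passing adjusted over the list alone, and the autophagy receptor gene Sqstm1 fell from 626 ± 25.3 to 390 ± 13.5 CPM (camera adjusted p = 0.030, and adjusted p = 0.27 with an estimated correlation). With library size only 10 rose and 8 fell and the call was lost (adjusted p = 0.34), as it was without siRalA replicate 2 (adjusted p = 0.051). Of 24 apoptosis and pyroptosis effectors, 4 rose and 10 fell, or 9 and 9 with library size only, where the median turned from -0.06 to 0.13, with 14 passing adjusted over the list alone, and the death receptor gene Fas fell from 72.7 ± 6.04 to 23.6 ± 1.18 CPM (camera adjusted p = 0.073). Of 30 secretory pathway and ER stress genes, 9 rose and 10 fell, or 20 and 4 with library size only, and 19 passed adjusted over the list alone (camera adjusted p = 0.91). In it Hsp90b1, an ER chaperone gene, fell from 1789 ± 54.2 to 1216 ± 28.5 CPM. Of 32 cytosolic ribosomal protein genes, 2 rose and 11 fell, or 19 and 1 with library size only, and 12 passed adjusted over the list alone (camera adjusted p = 0.99). Among them Rpl3 rose from 289 ± 11.9 to 663 ± 18.7 CPM. Without siNC replicate 2, 8 ribosomal protein genes passed. Of 13 mitochondrially encoded transcripts, 3 rose and 7 fell, or 3 and 2 with library size only, and 12 passed adjusted over the list alone (camera adjusted p = 0.67).

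Interferon-stimulated genes were uneven among the control libraries. Of 31 tested, 1 rose and 11 fell, with 11 passing adjusted over the list alone, and the list was not called (camera adjusted p = 0.34). The guanylate-binding protein gene Gbp2 fell from 58.8 ± 5.96 to 23.8 ± 2.47 CPM and Ifi44 from 26.5 ± 23.1 to 7.13 ± 1.99 CPM. With no filter on low counts Ifi44 was not called (edgeR adjusted p = 0.062). The summed level of the list was 1390 CPM in siNC 1, 770 and 700 CPM in siNC 2 and siNC 3, and 641 to 754 CPM in the siRalA libraries. Without siNC replicate 1, 3 rose and 9 fell, and the list median moved from -0.66 to -0.06. Without siRalA replicate 1, 7 members passed, and with no filter on low counts 4 passed.

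Markers of other cell types moved in both directions. Of 12 skeletal muscle markers, 8 rose and 1 fell, with 9 passing adjusted over the list alone, and the myosin gene Myh1 rose from 36.7 ± 3.58 to 107 ± 14.5 CPM (camera adjusted p = 0.0045, and adjusted p = 0.47 with an estimated correlation). All 7 adipocyte markers rose and 7 passed adjusted over the list alone, and Fabp4, a fatty acid carrier, rose from 53.5 ± 5.33 to 115 ± 11.3 CPM (camera adjusted p = 0.0017, and adjusted p = 0.23 with an estimated correlation). Among 17 macrophage and osteoclast markers, 3 rose and 5 fell, or 6 and 5 with library size only, where the median turned from -0.16 to 0.04, with 9 passing adjusted over the list alone, C1qc rising from 15.2 ± 0.501 to 28.7 ± 2.23 CPM and Itgam falling from 65.1 ± 1.47 to 22.9 ± 2.33 CPM. Among 17 synovial and fibroblast markers, 6 rose and 7 fell, or 8 and 6 with library size only, with 14 passing adjusted over the list alone. Dcn, the proteoglycan decorin, fell from 2959 ± 58.3 to 782 ± 65.1 CPM. Among 9 osteoblast and osteocyte markers, 3 rose and 2 fell, or 4 and 2 with library size only, with 7 passing adjusted over the list alone. Sp7 rose from 1.64 ± 0.501 to 6.49 ± 0.414 CPM. Of 12 smooth muscle and pericyte markers, 5 rose and 2 fell, or 8 and 2 with library size only, with 7 passing adjusted over the list alone. Myh11 rose from 2.31 ± 0.581 to 16.0 ± 1.26 CPM. Of 11 endothelial markers, 1 rose and 5 fell, or 3 and 4 with library size only, with 6 passing adjusted over the list alone. Tek fell from 4.34 ± 1.13 to 1.71 ± 0.116 CPM.

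The remaining marker lists were small. Of 7 tendon and ligament markers, 2 rose and 3 fell, or 3 and 2 with library size only, with 6 passing adjusted over the list alone. Scx fell from 22.0 ± 2.05 to 12.7 ± 0.355 CPM. Of 7 Schwann cell and neural markers, 2 rose and 1 fell, or 3 and 1 with library size only, with 3 passing adjusted over the list alone. S100b rose from 13.1 ± 0.166 to 21.7 ± 2.21 CPM. Of 4 epithelial markers, 1 rose and 2 fell, with 3 passing adjusted over the list alone. Krt19 fell from 13.6 ± 3.32 to 0.526 ± 0.240 CPM. Of 4 tested markers of other leukocytes, 1 rose and 0 fell, with 1 passing adjusted over the list alone, Kit being at 0.571 ± 0.159 and 1.51 ± 0.610 CPM. Without siRalA replicate 1 or siRalA replicate 3, 2 of these markers passed. No erythroid marker was abundant enough to test. None of these lists except the muscle and adipocyte lists was called by camera (adjusted p from 0.22 to 0.99).

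Over the 39 lists tested, camera called 20, of which 7 were higher and 13 lower, and 5 were called with an estimated correlation, namely cytokines, NF-kB, NRF2, p53, and prostaglandin and nitric oxide synthesis. The fry test called 30. The median and the camera direction differed in sign for the Ral, exocyst, ribosomal, other leukocyte, synovial, osteoblast and neural lists, none of which camera called, and the mean and the median differed in sign for the Ral, exocyst, synovial, osteoblast and neural lists. Of 736 tested list members, 210 were higher and 336 lower, where 51.1% of all tested genes were called.

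**Figure D2:**
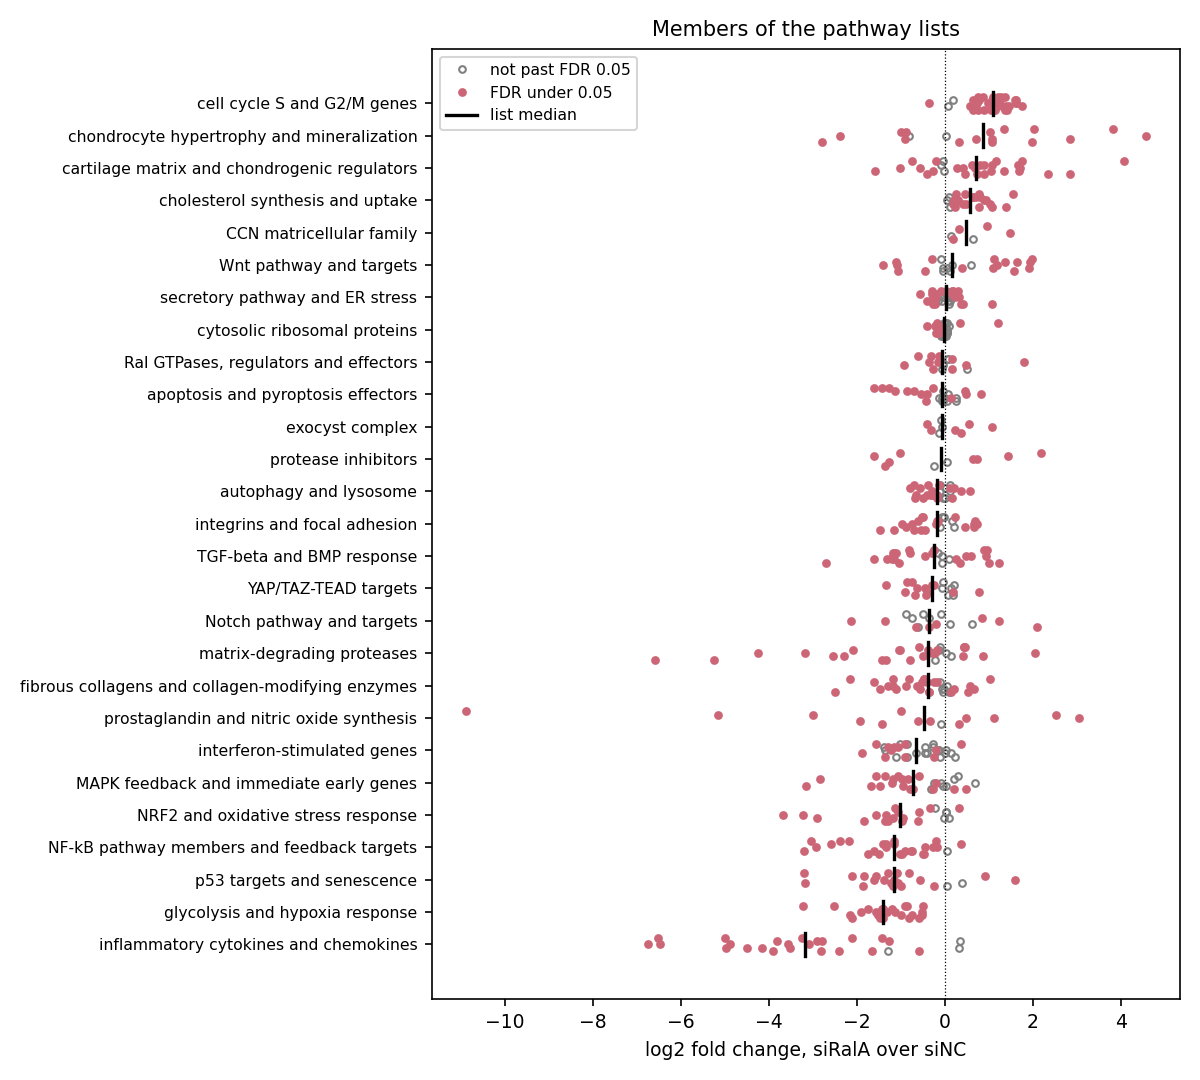
Log2 fold change of siRalA over siNC for every tested member of the pathway lists, ordered by list median, with filled points for members at an adjusted p under 0.05 vertical lines for medians, and Csf2, at 0 in every siRalA library, drawn at its bound. Inflammatory cytokines lie lowest with a median of -3.18 and cell cycle genes highest with 1.08, and with library size only the medians of the Ral, exocyst, protease inhibitor, apoptosis, autophagy, integrin and ribosomal lists turn positive.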

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

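The 9745 calls became 8720 to 10936 over the 15 other settings that kept the same null hypothesis, and 8720 to 9401 when single libraries were left out. Against a 1.5-fold change, glmTreat called 2786 genes, 1069 higher and 1717 lower, because that test asks for a larger effect. Library size only gave 7648 genes higher and 3288 lower, with a shift of 0.20 in the median log2 fold change that comes from leaving out the TMM factors. With it Rala had a log2 fold change of -0.17 (edgeR adjusted p = 0.051, against 1.3e-06 to 0.0055 over the other settings), and leaving out single libraries gave -0.40 to -0.32. Ccn3 kept its direction and call, from 1.39 to 1.67. The members of the lists that passed numbered 515 to 564 against 546. With an estimated correlation camera called 5 lists instead of 20, and without single libraries 18 to 20. With counts divided by 4, a setting chosen after seeing the data, 9501 genes were called.

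Some uncalled lists changed camera direction, and the cause was not tested. These were the Ral list (adjusted p = 0.99) and the ribosomal list (0.98) with RLE size factors, and the mitochondrial (0.72), other leukocyte (0.78) and synovial (0.99) lists with library size only. The same happened to the ribosomal list without siNC replicate 1 or 3 (0.92 and 0.95, in a range of 0.78 to 0.98 over the libraries left out) and to the other leukocyte list without siRalA replicate 1 (0.93, in a range of 0.93 to 0.999 over the libraries left out). Of the 166 genes covered by the naming rule, 0 reversed. Eng, Exoc2, Rpl13a and Tnmd lost their call with library size only, and Ifi44 and Zbp1 with no filter.

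The replicate numbers did not pair the libraries. Deviations from the group means correlated at 0.014, -0.018 and -0.011 between libraries of the same number, and 1 of 6 libraries correlated best with its own number. With the replicate block 9204 genes were called, and camera called 18 lists, the integrin and autophagy lists not being called (adjusted p = 0.0718 and 0.0502).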

Other observations

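Tests chosen only after their results were seen were the sums of macrophage genes, the part of the test of anatomical origin on single position genes, the search of the labels for a day or stimulation, the search for swapped libraries and the comparison of Y-linked genes, and the gene families were also picked after the data were seen. Of 24 gene families looked at, the imprinted genes had the smallest camera adjusted p (2.0e-10, and 0.18 with an estimated correlation). Of 18 imprinted genes, 11 were higher and 5 lower, where 51.1% of all tested genes were called. Their summed level rose from 8138 to 14367 CPM. The imprinted gene Mest, among the largest rises, itself went from 192 to 3339 CPM, and the family was picked after the data were seen. The aryl hydrocarbon receptor battery, genes of xenobiotic metabolism, had 4 of 6 members higher and 0 lower (camera adjusted p = 9.5e-05, and adjusted p = 0.18 with an estimated correlation). Mitochondrial ribosomal proteins were higher in 49 and lower in 2 of 81 genes, and proteasome subunits higher in 34 and lower in 5 of 48 (camera adjusted p = 0.0012 for both, and adjusted p = 0.18 and 0.20 with an estimated correlation). These 4 families kept a positive median with each other scaling.

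MHC class I heavy chain genes, whose products present peptides to T cells, were lower in 12 and higher in 0 of 16 (camera adjusted p = 7.4e-08, and adjusted p = 0.19 with an estimated correlation), with the limit that such genes share sequence. Complement components were lower in 10 and higher in 5 of 16, and their sum fell from 2715 to 1172 CPM (camera adjusted p = 0.012, and adjusted p = 0.23 with an estimated correlation). Small leucine-rich proteoglycans were higher in 7 and lower in 3 of 11 while their summed level went from 11223 to 8872 CPM (camera adjusted p = 0.0044, and adjusted p = 0.18 with an estimated correlation). Of the other 17 families, camera called the CCT chaperonin, tRNA synthetases, myosin heavy chains, Frizzled receptors and glucose transporters, and none of the 24 was called with an estimated correlation.

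The inflammatory and matrix-degrading genes were mostly lower in siRalA libraries. The siNC libraries held some of them at high levels, such as 2103 CPM of Nos2, and others at low levels, such as 1.18 CPM of Tnf and 0.379 CPM of Il1b. Whether leukocytes were fewer stays open, since the marker median of -0.16 (-1.18 to 0.25), the first test, decided nothing. The sum of the 17 markers was 0.783 times the siNC level (0.705 to 0.907 between single libraries), while that of 8 lineage genes among them was 1.27 times. A loss in proportion to the 17 markers would be smaller than the cytokine list median of -3.18 on the log2 scale, so it alone does not account for that fall. A loss limited to some leukocyte types was not tested. A few abundant genes distorting the scaling are argued against by the cytokine list median of -3.05 (-4.04 to -2.14) with the 50 most abundant genes left out of the library sizes. A difference between the groups in stimulation, day or culture other than the siRNA could give the same pattern, and 0 libraries have a label naming one, so it cannot be told apart from an effect of siRalA. That siRalA itself lowered these genes is the biological hypothesis and was not tested beyond the comparison.

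The groups differed in 9745 genes although Rala itself was 77.6% of its siNC level. Reads shared with copies of Rala are argued against by the 0% of 2868 distinct 31-base words of its transcripts found in transcripts of other genes. A swap of single libraries is argued against by a gap on the first principal component 13.3 times the wider range within a group. Cultures from different animals or dissections cannot be told apart from the siRNA. Y-linked genes summed to 209 to 230 CPM over the libraries, with a ratio of 0.959 and overlapping groups, and Xist was at 0.057 to 0.43 CPM. Both groups thus showed the pattern of male cells, and the comparison of Y-linked genes could not separate different male animals. The muscle and adipocyte markers had been seen before this test was written and decide nothing, as do the epithelial markers, with 1 higher and 2 lower.

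Hox genes, which pattern the body axis and limbs and are not used by the first branchial arch from which the condyle forms, were present in all 6 libraries. Their sum was 329 to 378 CPM, with Hoxa10 at 78.3 and 120 CPM and Tbx4, a hindlimb gene, at 60.3 and 45.2 CPM in siNC and siRalA. The ratio of summed Hox levels was 1.09 (1.01 to 1.15 between single libraries). Of 34 tested Hox genes, 4 were higher, 4 lower and 26 did not pass, where 51.1% of all tested genes were called. Ratios were 1.22 for the posterior Hox sum, 1.53 for Hoxa10, 1.17 for Hoxc10, 1.09 for Hoxa9 and 0.981 for Hoxa11. Outside the Hox genes they were 1.37 for Tbx5, 1.22 for Pitx1, 0.750 for Tbx4 and 2.71 for Dlx5. Cells of different anatomical origin in the groups stay open. Hoxa10, Tbx4, Tbx5 and Dlx5 each separated the groups, but they entered the test after their values were seen. The groups did not overlap for 60.3% of all tested genes either, so the separation of these genes decides nothing. Limb-derived cells in all cultures are a candidate explanation that stays open. First-arch and cranial genes reached 13.3 to 15.1% of the posterior Hox sum, over the bound of 10% set for it. Most of that came from Barx1, at 28.3 and 32.0 CPM of a summed 33.2 and 37.9 CPM in siNC and siRalA. The other genes of the sum were low, the highest group mean being 3.72 CPM for Dlx2 in siRalA. The first-arch genes Lhx6 and Lhx8 were outside the sum. They were at 0.435 and 0.201 CPM in siNC, and at 0.398 and 0.265 CPM in siRalA. The test therefore rests mostly on Barx1 and does not decide the origin of the cells. An earlier test on Hoxa10, Hoxa11 and Tbx4 themselves, whose lowest level was 39.1 CPM, was set aside because those genes had shown the pattern, and no library of known origin gives a background.

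The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05, and 1 of 10 splits, the real one, gave as many genes, list members or lists. The real split called 9745 genes, 546 list members and 20 lists, and the highest of the other splits called 0 genes, 0 list members and 12 lists. The other splits each called 10 to 12 lists. They mix libraries of both groups unevenly, so the group difference widens the spread within each part and some of it remains between the parts. Their 0 genes therefore say nothing about the cause of the difference, and their 10 to 12 lists give no background for the 20. Ccn3 transcript, for which the title names secretion driven by RalA, was 2.77-fold higher in siRalA libraries.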
